A study of Arabidopsis thaliana with 12 samples.

How the data were processed

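The deposited signal was the fluorescence intensity of 2 dyes, Cy3 and Cy5, scanned with Agilent Feature Extraction per the file headers. Per the file headers the scanner files also held a log10 ratio of both dyes, made by the scanner software after background subtraction and dye normalization, which was used here only as an alternative. The deposited summary table held a log2 ratio of Cy5 over Cy3, and it was equal within 5.0e-10 on all 12 arrays to normexp background correction with an offset of 50 followed by loess, computed from the median signals. Per the submitters' processing notes the table was made with limma, for which no version was given.

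Values were computed here from the scanner files with limma 3.58.1 in R 4.3.3. Median spot signals were corrected with normexp at an offset of 50, loess was fitted within each array, and control and outlier spots were given no weight. The median signal took the place of the mean signal that had been planned, because the summary table matched the median. Each array had 45220 spots, of which 43803 were not controls and stood for 43603 probes. The 50 probes printed on more than 1 spot were averaged. By the accession of each probe 34348 probes were matched to 1 gene, and the other 9255 probes were left out.

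For the 6946 genes with more than 1 probe the brightest probe over all arrays was used, out of 25410 genes with a probe. A gene was kept when both replicates of at least 1 of the 12 conditions were well above background, the scanner's own call, which left 20390 genes. The annotation served for names alone, since its build name differed from that in the file headers, so no coordinates are given. Where a fold set against a sample not well above background is written as at least N-fold, the true level of that sample may be lower than the one used. N leaves out the error of the fit, so it is not a confidence limit and does not by itself show a change of that size.

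All 12 arrays entered 1 limma model with 6 ratio terms, coded by the dye of the test sample, and 1 dye term common to all arrays. It had 5 residual degrees of freedom and 3.7 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. The 3 differences between ratio terms were tested in the same model. Conditions that were never hybridised together were compared by limma's separate-channel method over 20196 genes, with an intraspot correlation of 0.318. The same correlation was used where a smaller set of arrays gave no estimate.

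The genes, lists, tests, alternatives and named-gene rule were chosen before the data were examined, except for the additions named in the closing section. By this rule each direct comparison names AtERF#111, the 10 highest and the 10 lowest called genes with at least 2-fold change in the same direction on both arrays, and up to 4 called members per list, or up to 2 members as values where none was called. Differences name up to 5 genes per direction, or the 5 with the smallest p. Up to 10 genes per direction are named across comparisons, and fewer may be named anywhere.

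The 24 gene lists held 354 members, of which 352 had a probe and 344 passed the filter. They covered group X ERF factors, jasmonate biosynthesis, jasmonate repressors, signalling and catabolism, jasmonate and wound output, early wound and touch response, tryptophan and camalexin synthesis, indole and aliphatic glucosinolates, salicylic acid, ethylene, auxin, abscisic acid, low oxygen, root hair growth, photosynthesis, phenylpropanoids and lignin, flavonoids and anthocyanin, suberin, heat shock, wound-induced regeneration, and markers of root, epidermis, guard cells and vasculature. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes.

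The alternatives were no background correction, the scanner's log ratio, normexp without an offset, median centring in place of loess, scaling of the spread between arrays, no filter or a stricter filter on dim probes, outlier spots kept, no dye term, a dye term per slide (the slide block, which also blocks the replicate pairs), the 4 arrays of an experiment alone, array weights, the mean of all probes of a gene, the summary table's values, a 2-fold minimum and leaving out each array. Simulated 2-fold changes added to null data were recovered at 37% to 51% in the direct comparisons and 4-fold changes at 94% to 100%. Between 0 and 5 unchanged genes were called in these simulations. In the differences between ratio terms 5% to 15% of 2-fold and 84% to 92% of 4-fold changes were recovered. Each of these simulated differences held 200 genes changed 2-fold and 200 changed 4-fold, which eases the adjusted threshold. Where few genes truly differ, the share recovered would be lower. In the separate-channel comparisons these shares were 76% to 84% and 100%. Their simulated channel levels took all their spread from that of the log2 ratios, so levels that vary more between arrays are not covered. A simulated set of 15 genes shifted by 0.5 log2 was found in each direct comparison, and 0.4% to 2.2% of unshifted sets had a camera p under 0.05. The simulated genes varied independently, so these shares do not show how camera behaves on lists whose genes vary together.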

Results

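The series compared transcript levels in *Arabidopsis thaliana* plants or cells that differed in AtERF#111, also called ABR1 (AT5G64750), a transcription factor of the ERF family. Each of the 12 arrays carried a test sample and a control sample labelled with different dyes. They formed 6 direct comparisons of 2 arrays each, with the dyes swapped between both arrays. The first experiment compared overexpressor seedlings of 7 days with the wild type Col-0, separately in roots and shoots. Replicate 1 used the line ERF#111-OE2 and replicate 2 the line ERF#111-OE1, so line, replicate number and dye changed together. The second compared rosettes of 3 weeks at 3 h after wounding with unwounded ones, in Col-0 and in the knockout erf#111-2. The third used leaf protoplasts of erf#111-2 plants of 4 weeks, given a plasmid for ERF#111-HBD or, as the control, GFP-HBD. These were treated with dexamethasone (DEX) at 10 µM for 4 h after the solvent DMSO or after cycloheximide (CHX), a blocker of protein synthesis, at 50 µM.

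Each experiment lay on its own slide of 4 arrays. Between 19298 and 29863 probes per channel, 44.1% to 68.2%, were well above background, and the median signal was 1.22 to 5.47 times the local background. From 6 to 160 outlier spots per array were left out, and 0 spots were saturated. The number of arrays limits the precision. The labels do not say whether replicates came from separate plants, so p-values measure the spread between these samples alone. Across genes, which are not independent replicates, the log2 ratios of both replicates had a Pearson r of 0.924 for wounding in wild type and 0.86 in the knockout. It was 0.702 for protoplasts with DMSO and 0.357 with CHX, and 0.27 for overexpressor roots and 0.106 for overexpressor shoots. Spearman's rho, which large changes weigh on less, was 0.766, 0.622, 0.577, 0.125, 0.008 and -0.05 in the same order, so over most genes the seedling replicates did not agree. Residuals of the shared model had an SD of 0.214 on the root arrays and 0.347 and 0.348 on the shoot arrays. The other arrays had 0.146 to 0.202, so the shared spread may make seedling p-values too small, above all those of shoots.

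AtERF#111 itself served as a check of the labels. It was 11.3-fold higher in overexpressor roots (log2 3.47 and 3.52 on its 2 arrays, SE of the fitted value 0.19, adjusted p = 6.9e-05) and 6.57-fold higher in overexpressor shoots (2.72 ± 0.19, SE, n = 2 arrays, adjusted p = 0.00018). Wounding raised it 4.76-fold in wild type (2.25 ± 0.19, adjusted p = 7.8e-05). In the knockout its probe was not well above background in any of the 4 channels, and its log2 ratio was 0.07 ± 0.19. The ERF#111 plasmid raised it by 3.52 ± 0.19 with DMSO and by 3.34 ± 0.19, or 10.1-fold, with CHX. In knockout protoplasts given GFP the probe was nonetheless well above background, at 25.2 to 52.6 times the local background.

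**Figure D1:**
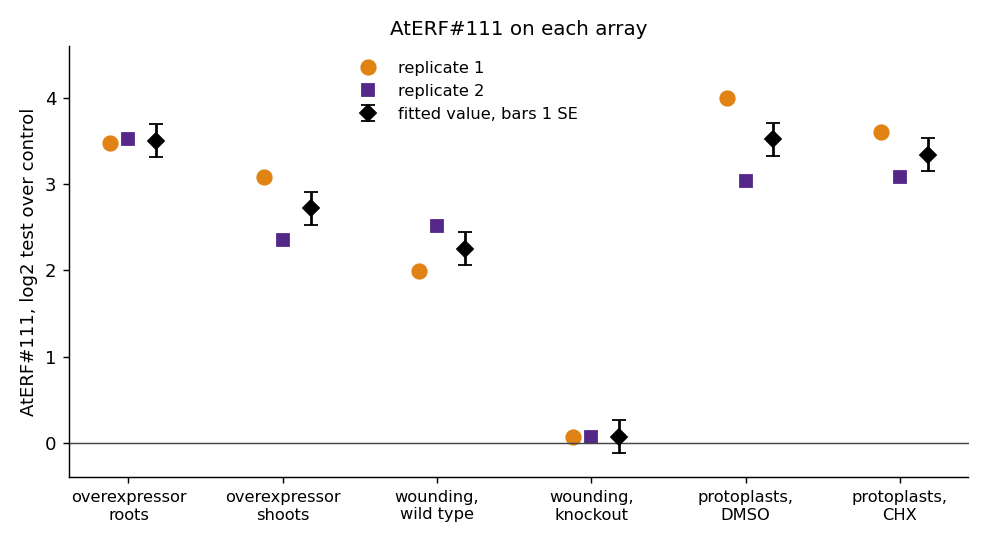
Log2 ratio of AtERF#111 in test over control samples for each of the 6 direct comparisons, with replicate 1 as circles, replicate 2 as squares and the fitted value as diamonds with bars of 1 SE. All arrays except both of the knockout wounding comparison, at 0.07, lie between 1.99 and 4.00.

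**Figure D2:**
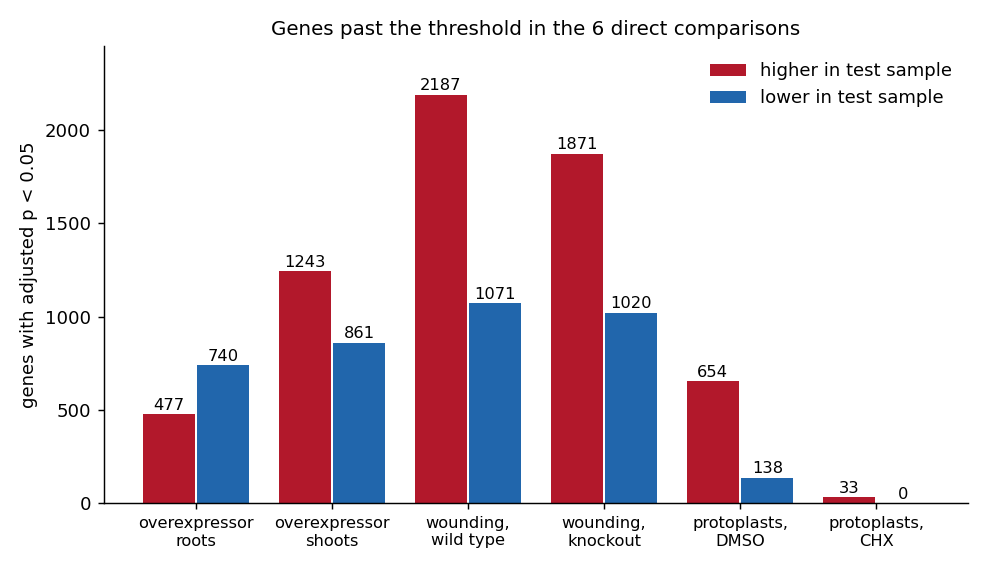
Number of called genes (vertical axis, adjusted p under 0.05) that were higher or lower in the test sample, for each of the 6 direct comparisons. The tallest pair of bars is wounding in wild type, with 2187 higher and 1071 lower, and the smallest is protoplasts with CHX, with 33 higher and 0 lower.

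The first question was which transcripts differ when AtERF#111 is overexpressed. In overexpressor roots the highest called genes were AT3G59930 (log2 4.51 ± 0.35, n = 2 arrays), AT5G44572 (4.41 ± 0.30), the high-affinity potassium transporter gene HAK5 (4.39 ± 0.21), AT4G12890 (4.33 ± 0.14) and AT5G44540 (4.17 ± 0.20). The cytochrome P450 genes CYP706A1 (4.08 ± 0.29) and CYP706A2 (4.04 ± 0.33) rose as well, as did the transcription factor genes WRKY66, at least 13.7-fold, and RAP2.9 (3.70 ± 0.23). TH8, a thioredoxin gene, had a mean of 3.75 ± 0.65 from unlike arrays at 5.38 and 2.12. The lowest were AT5G64120 (-2.88 ± 0.26), the iron transporter gene IRT1 (-2.84 ± 0.52), AT4G12170 (-2.69 ± 0.28), the ferric reductase gene FRO2 (-2.50 ± 0.54), AT5G64110 (-2.49 ± 0.24) and AT1G77530 (-2.49 ± 0.46). IRT1 and FRO2 stood at -4.03 and -4.19 in line ERF#111-OE2 and at -1.64 and -0.81 in line ERF#111-OE1, and AT1G77530 at -3.88 and -1.11 in the same order.

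Among the lists in roots, 4 of 24 measured genes for jasmonate repressors, signalling and catabolism rose and 1 fell (7 and 1 adjusted over the list alone). Examples that rose were JAZ8 (2.14 ± 0.30), JOX4 (2.52 ± 0.41) and CYP94B3 (3.15 ± 0.52), which act in hormone repression or breakdown. None of the 16 jasmonate biosynthesis genes was called, with a median of -0.02 that turned to 0.02 under median centring. Of 12 tryptophan and camalexin genes 5 rose (5 adjusted over the list alone), led by CYP79B2 (1.09 ± 0.20) and CYP71A12 (1.32 ± 0.26). Of 11 indole glucosinolate genes 3 rose (4 adjusted over the list alone), namely CYP81F2 (1.22 ± 0.14), UGT74B1 (0.77 ± 0.15) and MYB51 (0.83 ± 0.16). PLT5 (1.74 ± 0.17) and PSK5 (1.83 ± 0.24) rose among 9 wound-induced regeneration genes. RAB18, a dehydrin gene of the abscisic acid list, rose by 3.66 ± 0.25 and CYP707A3 by 1.68 ± 0.25, the 2 of its 17 genes that were called. Among 21 root hair growth genes 1 fell, LRL3 (-1.07 ± 0.20), and 6 fell adjusted over the list alone. Of 25 photosynthesis genes 2 rose, LHCB1.3 (1.56 ± 0.22) and GAPA (0.92 ± 0.16), and 8 adjusted over the list alone. Of 11 root marker genes 2 fell (3 adjusted over the list alone), IRT1 and the aquaporin gene TIP2;3 (-1.28 ± 0.31). Suberin genes had a median of -0.47 with 0 of 11 called by limma, 0 adjusted over the list alone, and MYB41 at -0.77 ± 0.23.

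Of 20314 genes tested in roots 1217 were called, 477 higher and 740 lower. Camera found 6 lists beyond other genes, which were root hair growth (median -0.33, adjusted p = 0.00057), photosynthesis (0.40, 0.00074), indole glucosinolates (0.52, 0.0032), tryptophan and camalexin synthesis (0.22, 0.0094), suberin (-0.47, 0.014) and root markers (-0.21, 0.028). All 6 were lost, each with adjusted p = 0.42 with an estimated correlation, fry kept indole glucosinolates and root markers alone of the 6, and root markers had 0.052 with the slide block. On replicates 1 and 2 the medians were -0.09 and -0.73 for root hair growth, 0.72 and 0.19 for photosynthesis, 0.63 and 0.10 for indole glucosinolates and -0.66 and -0.18 for suberin. Without replicate 1 the count was 261 and without replicate 2 it was 637. The slide block gave 2310 genes and the 4 arrays of the slide alone 534, the latter including 490 of the 1217. Median centring turned the split to 444 higher and 238 lower and shifted the median of all genes by 0.18, and the scanner's log ratio gave 331 higher and 264 lower.

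In overexpressor shoots genes for plant defensins, small antimicrobial proteins, were among the highest. PDF1.2c rose by log2 6.91 ± 0.54 (n = 2 arrays), PDF1.3 by 6.48 ± 0.31, PDF1.2b by 6.12 ± 0.57 and PDF1.2 by 4.48 ± 0.27. The sequences of these paralogs are near-identical, so their probes cannot be assigned to one of them with certainty. AT3G59930 (6.37 ± 0.35), AT2G19970 (5.69 ± 0.26), TH8 (5.09 ± 0.65), AT5G33355 (4.86 ± 0.32), HAK5 (4.24 ± 0.21) and AT5G44540 (4.23 ± 0.20) were also among the highest. Among the lowest were HIS1-3 (-3.21 ± 0.14), a linker histone gene, AT1G66100 (-2.89 ± 0.54), AT14A (-2.52 ± 0.60), AT2G37030 (-2.38 ± 0.14), AT5G03120 (-2.37 ± 0.24), the thionin gene THI2.2 (-2.33 ± 0.30) and the expansin gene EXPA2 (-2.14 ± 0.23). The arrays were unlike for AT1G66100, at -4.54 and -1.25, for AT14A, at -4.57 and -0.47, for PDF1.2c, at 8.54 and 5.29, and for PDF1.2b, with replicate 1 at 7.83. For PDF1.2c, PDF1.2b, PDF1.2, HAK5 and AT5G44540, and for SAD6, COBL9 and TT8 below, the control was well above background on 1 of the 2 arrays alone, so their values are less certain.

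In the shoots 5 of 11 indole glucosinolate genes rose (6 adjusted over the list alone), such as CYP81F2 (2.71 ± 0.14), IGMT2 (1.56 ± 0.22) and UGT74B1 (1.01 ± 0.15). Of 12 tryptophan and camalexin genes 6 rose, over all genes and adjusted over the list alone, with GSTF6 at 3.11 ± 0.29. Of 17 low oxygen genes 7 rose (8 adjusted over the list alone), such as WIP4 (1.75 ± 0.15), SAD6 (1.99 ± 0.38) and PDC1, at least 2.73-fold. Of 21 root hair growth genes 5 rose (7 adjusted over the list alone), such as RHS13 (1.66 ± 0.18) and COBL9 (1.08 ± 0.14). Suberin genes went both ways, with 4 of 11 lower and 2 higher (7 and 2 adjusted over the list alone), such as ASFT (-1.19 ± 0.14) and CYP86A1 (0.83 ± 0.19). Of 24 jasmonate repressor, signalling and catabolism genes 5 rose and 3 fell (6 and 4 adjusted over the list alone), with JOX2 (2.29 ± 0.19) and JOX3 (2.48 ± 0.28) higher and JAZ7 (-1.55 ± 0.19) lower. Of 16 jasmonate biosynthesis genes JAR1 rose (1.35 ± 0.21) and AOS fell (-0.70 ± 0.14). Of 18 jasmonate and wound output genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), with CHI-B, a chitinase gene, at 1.61 ± 0.16 beside the defensins. Of 20 auxin genes 2 rose and 4 fell, over all genes and adjusted over the list alone, with TAA1 at 1.12 ± 0.17 and IAA29 at -1.85 ± 0.17. Of 17 ethylene genes 4 rose and 3 fell (4 and 4 adjusted over the list alone), with ETR2 at 1.00 ± 0.17 and ACS11 at -0.59 ± 0.12. WIND3 (1.69 ± 0.31) and PSK5 (1.58 ± 0.24) rose among the regeneration genes, and BGLU21 and BGLU22 were the 2 of 11 root markers that rose.

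Of 20274 genes tested in shoots 2104 were called, 1243 higher and 861 lower. Camera found 7 lists, higher for root hair growth (median 0.45, adjusted p = 8.3e-06), low oxygen (0.61, 2.6e-05), indole glucosinolates (0.84, 5.7e-05), tryptophan and camalexin synthesis (0.69, 0.00016) and wound-induced regeneration (0.42, 0.036), and lower for abscisic acid response (-0.31, 0.0087) and suberin (-0.70, 0.0087). These had adjusted p = 0.26 to 0.39 with an estimated correlation, and all 7 passed fry. Of the 17 abscisic acid genes 0 were called by limma, over all genes or adjusted over the list alone, and their median was -0.08 under median centring. On replicates 1 and 2 the medians were 0.71 and 0.34 for low oxygen, 1.21 and 0.61 for indole glucosinolates, -0.43 and -0.96 for suberin and 0.45 and 0.18 for regeneration. Phenylpropanoid genes joined them with the slide block. The count was 1901 without replicate 1 and 5623 without replicate 2, which turned the split to 2557 higher and 3066 lower, and it was 4851 with the slide block, 915 from the 4 arrays of the slide alone and 65 with array weights. Median centring shifted the median of all genes by 0.25 and gave 2473 higher and 174 lower, and the scanner's log ratio gave 905 higher and 326 lower.

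Roots and shoots were then compared in their response to overexpression. The defensin genes PDF1.2c (log2 -6.64 ± 0.77), PDF1.3 (-6.21 ± 0.44), PDF1.2b (-5.95 ± 0.81) and PDF1.2 (-4.48 ± 0.38), and AT2G14247 (-3.76 ± 0.73), had lower overexpressor to wild type ratios in roots than in shoots. In roots PDF1.2b and PDF1.2 were not well above background in either sample and PDF1.2c not in the control, so the sizes of these 3 differences are not exact. RAB18 (3.89 ± 0.35), the expansin gene EXP3 (3.58 ± 0.29), CYP706A1 (3.41 ± 0.41), CYP706A2 (3.01 ± 0.47) and LEA18 (3.01 ± 0.34) had higher ratios in roots. These differences are signed, so they can stem from opposite responses as well as from unlike sizes. Of 21 root hair growth genes 7 had lower ratios in roots (13 adjusted over the list alone), such as RHS13 (-2.23 ± 0.25), COBL9 (-1.32 ± 0.19) and RHS18 (-1.09 ± 0.17). WIP4 (-1.60 ± 0.21) and HRE2 (-1.01 ± 0.19) were among 3 of 17 low oxygen genes with lower ratios in roots (6 adjusted over the list alone), HRE2 with a shoot control not well above background. JAZ7 (2.03 ± 0.27), which fell in shoots, and JAZ6 (1.72 ± 0.34) had higher ratios in roots, and JOX2 (-3.11 ± 0.27), which rose in shoots, had a lower one. AtERF#111 differed by 0.78, with a 95% interval from 0.18 to 1.38 (adjusted p = 0.16).

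Of 20211 genes 863 were called in this difference, 274 above and 589 below 0. Camera found 6 lists, below 0 for root hair growth (median -1.07, adjusted p = 7.8e-10), low oxygen (-0.50, 0.00023), phenylpropanoids and lignin (-0.42, 0.004, with CYP98A3 at -1.31 ± 0.49) and root markers (-0.96, 0.0046, with BGLU21 at -2.41 ± 0.34). Above 0 were photosynthesis (0.60, 0.00042, with GAPA at 1.07 ± 0.23) and abscisic acid response (0.39, 0.0011). None was kept with an estimated correlation, with adjusted p = 0.24 to 0.30, and fry kept 4 of the 6, without photosynthesis and phenylpropanoids. The 4 arrays of the slide alone gave 0 genes by limma, with 3677 at an unadjusted p under 0.05, and the slide block gave 2480. Leaving out OE_root replicate 1 gave 277, OE_root replicate 2 gave 386 and OE_shoot replicate 2 gave 4419, with the split turned to 2358 above and 2061 below 0. Median centring gave 35 above and 231 below 0.

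The next question was how rosettes respond to wounding and whether the response needs AtERF#111. In wild type the ribonuclease gene RNS1 rose by log2 8.73 ± 0.31 (n = 2 arrays) and NATA1, for an ornithine N-acetyltransferase, by 8.61 ± 0.37. For RNS1, and for ILL6 and HSFA2 below, the control was well above background on 1 of the 2 arrays alone, so their values are less certain. AT2G38240, listed as JOX4 and encoding a jasmonate oxidase, rose by 8.02 ± 0.41, the vegetative storage protein gene VSP2 by 6.79 ± 0.41, the lipid transfer protein gene LTP2 by 6.78 ± 0.30 and the beta-amylase gene BAM5 by 6.63 ± 0.20. RAP2.6 (ERF108) rose at least 89-fold, AT1G10585 by 6.20 ± 0.15, the beta-glucosidase gene BGLU18 by 6.17 ± 0.56 and AT3G22620 at least 71.9-fold. The expansin gene EXPA8 (-3.91 ± 0.28) and GASA6 (-3.74 ± 0.21) fell most. AT1G19960 (-3.43 ± 0.28), AT5G03350 (-2.96 ± 0.35), ACD6 (-2.87 ± 0.42), APT2 (-2.85 ± 0.17) and PCC1 (-2.78 ± 0.57) fell as well.

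Of 16 jasmonate biosynthesis genes 13 rose in wild type, over all genes and adjusted over the list alone, such as AOC1 (6.03 ± 0.21), LOX3 (4.91 ± 0.20) and OPR3 (4.03 ± 0.17). Of 24 jasmonate repressor, signalling and catabolism genes 19 rose (20 adjusted over the list alone), such as JOX2 (5.60 ± 0.19) and ILL6 (3.47 ± 0.17). Of 18 output genes 12 rose and 1 fell, over all genes and adjusted over the list alone, including ANAC019 (4.42 ± 0.16) and CORI3 (5.10 ± 0.30). Of 17 abscisic acid genes 12 rose (13 adjusted over the list alone), such as KIN1 (4.79 ± 0.17), RD29A (3.97 ± 0.24), COR15A (4.16 ± 0.33) and AFP1 (2.89 ± 0.24). Of 12 tryptophan and camalexin genes 10 rose, over all genes and adjusted over the list alone, with TSA1 at 3.37 ± 0.18 and GSTF6 at 4.72 ± 0.29. Of 21 early wound and touch genes 11 rose (13 and 1 lower adjusted over the list alone), such as WRKY18 (4.70 ± 0.29) and ZAT10 (4.35 ± 0.51). Besides RAP2.6 and AtERF#111, ERF114 (at least 15.8-fold) and ERF113 (at least 2.04-fold) rose among 7 group X ERF genes. SOT16 (2.47 ± 0.27) and UGT74B1 (1.59 ± 0.15) were among 3 of 11 indole glucosinolate genes that rose (4 adjusted over the list alone). FAR1 (4.24 ± 0.17) was among 3 of 11 suberin genes that rose and PSK5 (3.56 ± 0.24) and WIND1 (1.55 ± 0.19) among 3 of 9 regeneration genes, each over all genes and adjusted over the list alone. CAD5 (5.08 ± 0.27), ADH1 (3.57 ± 0.19), PAP1 (2.88 ± 0.43) and CER3 (3.11 ± 0.18) rose from the lignin, low oxygen, anthocyanin and epidermis lists, whose tests did not pass camera.

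Of 20384 genes tested 3258 were called in wounded wild type, 2187 higher and 1071 lower. Camera found 12 lists. Of these, 6 were kept with an estimated correlation, each higher, namely jasmonate biosynthesis (median 2.55, adjusted p = 1.4e-13, then 0.015), jasmonate repressors (2.04, 5.8e-16, 0.029), output (2.26, 2.2e-09, 0.015), tryptophan and camalexin synthesis (2.23, 2.9e-10, 0.044), abscisic acid (1.54, 1.1e-10, 0.015) and group X ERF factors (1.03, 8.8e-05, 0.036). The others had adjusted p = 0.18 to 0.49 with an estimated correlation, and photosynthesis was also lost by fry (0.093). They were early wound and touch response (median 1.04, adjusted p = 1.1e-05), indole glucosinolates (0.20, 0.035), suberin (0.11, 0.037), regeneration (0.14, 0.035) and heat shock (0.19, 0.048, with HSFA2 at 1.24 ± 0.17), all higher, and photosynthesis (-0.25, 0.014, with PRK at -0.97 ± 0.14), lower. On replicates 1 and 2 the medians were 0.13 and -0.07 for suberin, 0.13 and 0.31 for regeneration and 0.16 and 0.30 for heat shock. With the scanner's log ratio and without an offset they were 0.82 and 0.79 for regeneration and 1.43 and 0.64 for heat shock, so these sizes depend on the processing. Suberin had adjusted p = 0.072 with the slide block, 0.099 from the slide alone and 0.082 without the seedling slide. Indole glucosinolates had 0.05 after rounding from the slide alone, at the threshold, and 0.055 without the seedling slide. Regeneration did not pass from the slide alone (0.084). The count was 1218 without replicate 1 and 864 without replicate 2. The slide block gave 5105 and the 4 arrays of the slide alone 7134, both with all 3258 genes among them. Median centring gave 2484 higher and 262 lower.

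In the knockout RNS1 rose at least 504-fold, NATA1 by 8.79 ± 0.37 (n = 2 arrays), AT2G38240 by 8.17 ± 0.41, LTP2 by 7.43 ± 0.30, BAM5 by 7.04 ± 0.20, AT4G17470 by 6.67 ± 0.88, BGLU18 by 6.64 ± 0.56, RAP2.6 at least 97.7-fold and VSP2 by 6.53 ± 0.41. GASA6 (-4.23 ± 0.21), EXPA8 (-4.18 ± 0.28), AT1G19960 (-3.64 ± 0.28), AT5G03350 (-3.21 ± 0.35) and APT2 (-2.70 ± 0.17) fell. Of 16 jasmonate biosynthesis genes 13 rose, over all genes and adjusted over the list alone, with AOC1 at 6.16 ± 0.21. Of 24 repressor, signalling and catabolism genes 18 rose (20 adjusted over the list alone), with JOX2 at 5.56 ± 0.19. Of 17 abscisic acid genes 9 rose (12 adjusted over the list alone), with KIN1 at 4.65 ± 0.17. ERF114 rose at least 16.9-fold and ERF113 at least 1.99-fold. Of 20387 genes 2891 were called, 1871 higher and 1020 lower, and camera found 10 lists, all of them also found in wild type, where indole glucosinolates and heat shock passed as well. With an estimated correlation 5 were kept, and group X ERF factors had adjusted p = 0.056, while fry kept 9 of the 10, without photosynthesis. In the knockout indole glucosinolates passed by fry, and heat shock passed camera with the slide block and from the slide alone. A difference of these lists between genotypes is therefore not shown. Suberin had 0.074 from the slide alone and 0.061 without the seedling slide. The count was 835 without replicate 1, 1057 without replicate 2, 4656 with the slide block and 6493 from the 4 arrays of the slide alone.

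**Figure D3:**
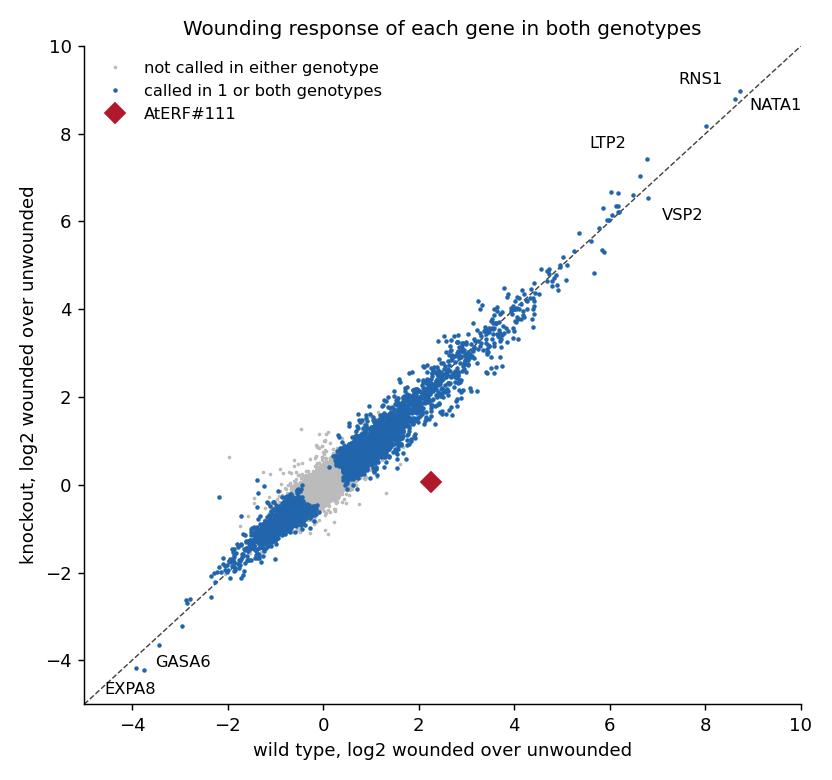
Log2 ratio of wounded over unwounded rosettes for each gene in wild type (horizontal axis) and in the knockout (vertical axis), with genes called in 1 or both genotypes in blue, the others in grey, AtERF#111 as a red diamond and the line of equal response dashed. Genes lie along the line, with r = 0.956, while AtERF#111 lies at 2.25 and 0.07.

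Both wounding responses were similar across genes, but the test of their difference had little power for small differences and did not call even AtERF#111. Across genes, which are not independent replicates, their r was 0.956, and 2505 genes were called in both, all in the same direction. Another 753 were called in wild type alone and 386 in the knockout alone, which does not show a difference by itself. In the test of the difference 0 of 20381 genes passed by limma, with 121 at an unadjusted p under 0.05 where 1019 are expected by chance, and the median 95% interval reached 0.57 log2, or 1.48-fold, to each side. Of simulated 2-fold differences 5% were recovered in this test. The fitted difference was at least 1 log2 for 35 genes, so the absence of calls does not show that single genes responded alike. The 5 genes with the smallest p, given as values, were AtERF#111 (-2.18, 95% interval -2.78 to -1.57, adjusted p = 0.46), AT5G50360 (-0.95 ± 0.18), AT2G05540 (-1.11 ± 0.21), LEA7 (-1.08 ± 0.23) and APC3 (-0.75 ± 0.17). AtERF#111 in both knockout samples, and AT5G50360, LEA7 and HAI1 in the unwounded samples of both genotypes, were not well above background, so these sizes are not exact. The slide block and the slide alone gave 0 genes too by limma, with 392 and 1270 at an unadjusted p under 0.05. Without the seedling slide AtERF#111 passed alone (adjusted p = 0.038), and over 18 alternatives its adjusted p ran from 0.0022 to 1, with all values below 0. Abscisic acid response was the list that camera found (median -0.40, adjusted p = 4.7e-07). It had adjusted p = 0.078 with an estimated correlation and 0.40 by fry, and median centring shifted the median of all genes by -0.18. Of its 17 genes 15 had values below 0, led by HAI1 (-0.94 ± 0.31), AFP1 (-0.77 ± 0.33) and ABI1 (-0.73 ± 0.48), and 0 were called by limma, over all genes or adjusted over the list alone. Jasmonate biosynthesis (median -0.10), jasmonate repressors (-0.11) and output (-0.09) did not pass. Group X ERF factors did not either, with a median of 0.03 above a mean of -0.31 that AtERF#111 carried.

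The genotypes were also compared directly, by separate channels. In unwounded rosettes 0 genes passed by limma, with 128 at an unadjusted p under 0.05 (1010 expected by chance), and the smallest p were those of AT2G05540 (1.04 ± 0.17), AT1G68600 (-0.75 ± 0.13), MRD1 (at least 2.38-fold higher), AGL87 (at least 1.6-fold lower) and UMAMIT36 (-1.25 ± 0.29). Leaving out wound_erf111 replicate 1 or wound_WT replicate 2 gave 5 genes each. In wounded rosettes 0 passed by limma, with 215 at an unadjusted p under 0.05 (1010 expected by chance), led by AT1G09500 (-1.33 ± 0.20), AT5G50360 (-1.10 ± 0.20), MRD1 (at least 2.55-fold higher) and AT2G42560 (-1.47 ± 0.30). AtERF#111, not well above background in the knockout, was at least 10.3-fold lower there in wounded (adjusted p = 0.73) and at least 2.27-fold lower in unwounded rosettes (adjusted p = 1), and did not pass in either. The absence of calls therefore does not exclude large differences between the genotypes. Leaving out wound_erf111 replicate 1 gave 19 genes, wound_WT replicate 2 gave 2 and wound_erf111 replicate 2 gave 1. Abscisic acid genes had a median of -0.32 in wounded rosettes (camera adjusted p = 4.7e-07, HAI1 at -1.03 ± 0.27) and 0.01 in unwounded ones (adjusted p = 0.70). Jasmonate repressors were lower in wounded rosettes by camera too (-0.15, adjusted p = 0.027). Group X ERF factors passed camera there as well, carried by AtERF#111, and without it the other 6 genes had a median of -0.01, with 3 of them below 0, and did not pass in a test chosen after the data were seen. An estimated correlation is not offered for separate channels. The slide alone gave 0 genes in both conditions by limma, with 265 in unwounded and 476 in wounded rosettes at an unadjusted p under 0.05.

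The protoplast experiment asked, per its stated design, which genes are direct targets. With DMSO the expansin gene EXPA1 rose most with ERF#111, by log2 7.54 ± 0.21 (n = 2 arrays), before AT2G17850 (6.76 ± 0.28), AT4G36850 (5.73 ± 0.34), AT2G34350 (at least 32.1-fold), SS3 of the strictosidine synthase family (4.74 ± 0.18) and the defensin gene LCR67 (4.45 ± 0.12). AT5G44572 (4.36 ± 0.30), AT5G21280 (3.91 ± 0.22), AT5G44575 (3.89 ± 0.15) and AT5G62730 (at least 14.4-fold) followed. The control was well above background on 1 of the 2 arrays alone for AT2G17850, AT4G36850, AT5G44572 and IGMT2, as it was with CHX for AT2G17850 and GPAT7. Decreases were small, with ARPN at -1.31 ± 0.24, UMAMIT42 at -1.26 ± 0.27, RLP34 at -1.20 ± 0.23, FAMT at -1.18 ± 0.26, the homoterpene synthase gene CYP82G1 at -1.10 ± 0.17 and IDA, for an abscission peptide, at -1.10 ± 0.19. Of 11 indole glucosinolate genes 4 rose (9 adjusted over the list alone), namely IGMT2 (3.36 ± 0.22), IGMT1 (2.21 ± 0.44), MYB122 (1.06 ± 0.24) and CYP81F2 (0.60 ± 0.14). ST2A, a jasmonate sulfotransferase gene, rose by 3.40 ± 0.25, JAR1 by 1.47 ± 0.21, ERF114 by 1.05 ± 0.20, COR15A by 1.60 ± 0.33 and PDC1 by 1.38 ± 0.25. EDS5 was the 1 of 15 salicylic acid genes that fell (-0.72 ± 0.14, 3 adjusted over the list alone). SOT18 (0.94 ± 0.13) and SOT17 (0.53 ± 0.12) rose among 12 aliphatic glucosinolate genes, over all genes and adjusted over the list alone.

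Of 20389 genes 792 were called with DMSO, 654 higher and 138 lower. Camera found indole glucosinolates (median 0.60, adjusted p = 3.9e-06) and heat shock (0.60, 9.4e-05) higher and salicylic acid response (-0.24, 0.00017) lower. They had adjusted p = 0.30, 0.67 and 0.89 with an estimated correlation, and fry kept the first alone. On replicates 1 and 2 the medians were 0.98 and 0.38 for indole glucosinolates, 0.53 and 0.66 for heat shock and -0.26 and -0.46 for salicylic acid response. Heat shock had 0 of 11 genes called by limma and 8 adjusted over the list alone, with HSP70 at 1.23 ± 0.44. The count was 67 without replicate 1 and 163 without replicate 2. The slide block gave 2346, the 4 arrays of the slide alone 3909 and the fit without the seedling slide 4260, each with all 792 among them. Median centring gave 425 higher and 16 lower, and scaling the spread between arrays 1402 and 623.

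With CHX, where new protein synthesis is blocked, 33 of 20379 genes were called, all higher. LCR67 rose by log2 5.27 ± 0.12 (n = 2 arrays), EXPA1 by 5.17 ± 0.21, AT2G17850 by 5.11 ± 0.28 and the cytochrome P450 genes CYP71B22 and CYP71B21 by 4.43 ± 0.28 and 3.92 ± 0.14. PRR1, for a pinoresinol reductase, rose by 3.83 ± 0.21, PXMT1 by 2.93 ± 0.29, the acyltransferase gene GPAT7 by 2.47 ± 0.18 and AT1G56130 by 2.46 ± 0.27. Of the 33 genes 25 were also higher with DMSO, 18 in overexpressor roots, 20 in overexpressor shoots, 11 in wounded wild type and 8 in the wounded knockout, while 2 were lower in both wounded genotypes, EXPA1 and HCF101. In roots, shoots and DMSO protoplasts alike 12 were higher, among them EXPA1, AT2G17850, PXMT1, GPAT7 and SS3. AtERF#111 itself is among the 33, these 12 and the genes also higher with DMSO, in roots, in shoots and in wounded wild type. In all but the last of these the design raised it. Besides AtERF#111 no group X ERF gene was called, and 0 of 11 indole glucosinolate genes by limma (2 adjusted over the list alone), with IGMT1 at 1.90 ± 0.44 and IGMT2 at 1.54 ± 0.22.

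**Figure D4:**
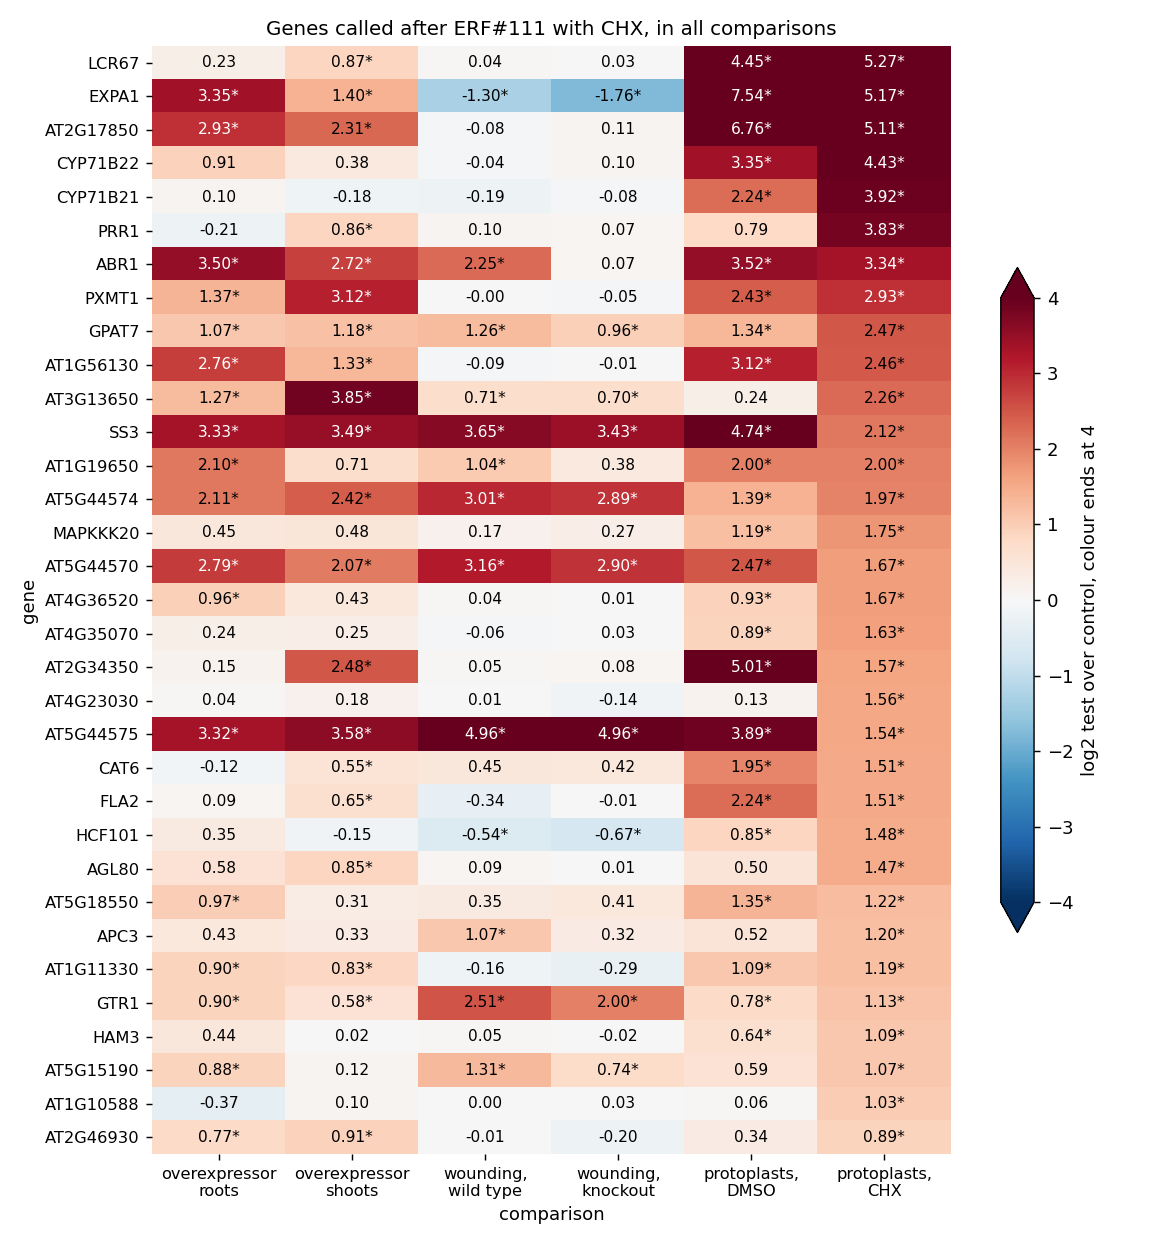
Log2 ratio (colour and number) of the 33 genes called in protoplasts with CHX, ordered from the highest, in each of the 6 direct comparisons, with asterisks on called values. EXPA1 is higher in 4 comparisons and lower in both wounding comparisons, and SS3, AT5G44570, AT5G44574 and AT5G44575 are higher in all 6.

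Camera found 8 lists higher with CHX, led by indole glucosinolates (median 0.14, adjusted p = 0.00011), photosynthesis (0.16, 0.0072) and group X ERF factors (0.23, 0.00016), a list that holds AtERF#111 itself. Without AtERF#111 the other 6 group X genes had a median of 0.22 (p = 0.024 by camera, 0.069 with an estimated correlation and 0.078 by fry), in a test chosen after the data were seen. Ethylene (0.14, 0.025, with ACS2 at 0.95 ± 0.17), phenylpropanoids (0.16, 0.025), heat shock (0.16, 0.025), early wound response (0.21, 0.033) and tryptophan synthesis (0.12, 0.048) followed. The lists had adjusted p = 0.16 to 0.71 with an estimated correlation, and fry kept 1 of the 8, the one that holds AtERF#111. On replicates 1 and 2 the medians were 0.24 and -0.01 for tryptophan synthesis, 0.30 and 0.06 for photosynthesis, 0.05 and 0.37 for heat shock, 0.32 and 0.10 for group X ERF factors and 0.08 and 0.28 for phenylpropanoids, so these rest mainly on 1 array each. With the slide block early wound response had adjusted p = 0.07 and tryptophan synthesis 0.10, and the latter had 0.053 from the slide alone and 0.12 without the seedling slide. The count of 33 became 12, of which 4 were lower, without replicate 1 and 7 without replicate 2. It was 89 with the slide block, 334 from the 4 arrays of the slide alone and 286 without the seedling slide, each with all 33 among them. At an unadjusted p under 0.05 there were 697 genes, where 1019 are expected by chance. That number was 1425 with the slide block, 2064 from the slide alone and 2281 without the seedling slide, so it depends on the model.

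Both treatments were compared in the response to ERF#111. PRR1 (log2 3.04 ± 0.30), AT3G13650 (2.02 ± 0.26), CYP71B21 (1.68 ± 0.19) and AT4G23030 (1.43 ± 0.21) responded more with CHX. AT4G36850 (-5.47 ± 0.48), AT5G44572 (-3.56 ± 0.42), AT2G34350 (-3.43 ± 0.20), ST2A (-3.36 ± 0.35) and AT5G21280 (-3.34 ± 0.30) were among 36 genes with lower ratios with CHX. The control was not well above background with DMSO for PRR1, CYP71B21 and AT4G23030, with CHX for AT5G21280 and in both for AT2G34350, and on 1 of the 2 arrays alone in one treatment for AT3G13650, AT4G36850, AT5G44572 and ST2A, so the sizes of these differences are not exact. AtERF#111 itself differed by -0.18, with a 95% interval from -0.79 to 0.42. Of 20378 genes 40 were called. Camera found 8 lists, above 0 for jasmonate biosynthesis (median 0.23, adjusted p = 0.0041), salicylic acid (0.28, 0.0041), ethylene (0.21, 0.0049), tryptophan synthesis (0.22, 0.041), jasmonate repressors (0.20, 0.042, in spite of ST2A) and jasmonate output (0.19, 0.042). Below 0 were indole glucosinolates (-0.30, 0.0041, IGMT2 at -1.81 ± 0.32) and heat shock (-0.47, 0.0041). They had adjusted p = 0.34 to 0.59 with an estimated correlation and 0.44 to 0.94 by fry. Leaving out proto_DMSO replicate 1 gave 4 genes and replicate 2 gave 16, and without either proto_CHX replicate 0 passed by limma. The slide block gave 108, the slide alone 699 and the fit without the seedling slide 826, each including all 40. Median centring gave 3 above and 12 below 0, and scaled spreads 34 above and 132 below.

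CHX alone, in protoplasts given GFP, changed 7189 of 20196 genes, 3251 higher and 3938 lower. AT1G06135 rose at least 318-fold, WRKY30 by log2 8.13 ± 0.18, ERF13 by 8.06 ± 0.94, ESE1 at least 248-fold and AT4G14450 by 7.81 ± 0.43 (n = 2 channels each), and WRKY30 was well above background on 1 of the 2 arrays alone with DMSO. The glutamine synthetase gene GSR2 (-4.67 ± 0.31), AT5G43570 (-4.53 ± 0.70), the RNA-binding protein gene GRP7 (-4.47 ± 0.32), the auxin conjugation gene GH3.17 (-4.27 ± 0.37) and the protease gene RD21A (-3.96 ± 0.26) fell. Of 21 early wound and touch genes 19 rose, over all genes and adjusted over the list alone (camera adjusted p = 8.7e-08), such as WRKY53 (at least 39.9-fold) and TCH4 (4.77 ± 0.49). Of 15 salicylic acid genes 11 rose and 1 fell, over all genes and adjusted over the list alone (0.00016), such as ICS1 (4.67 ± 0.52). Of 13 phenylpropanoid genes 11 fell (12 adjusted over the list alone, 4e-07), such as COMT1 (-3.82 ± 0.28). ERF112 (4.47 ± 0.21) and ERF109 (4.96 ± 0.56) were among 4 of 7 group X ERF genes that rose, while 1 fell (camera 0.0041), and LOX4 (5.30 ± 0.28) rose while LOX2 (-3.34 ± 0.34) fell among jasmonate biosynthesis genes (0.048). The 4 arrays of the slide alone gave 1567 genes and turned the split to 986 higher and 581 lower, and leaving out single arrays gave 5757 to 6567.

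**Figure D5:**
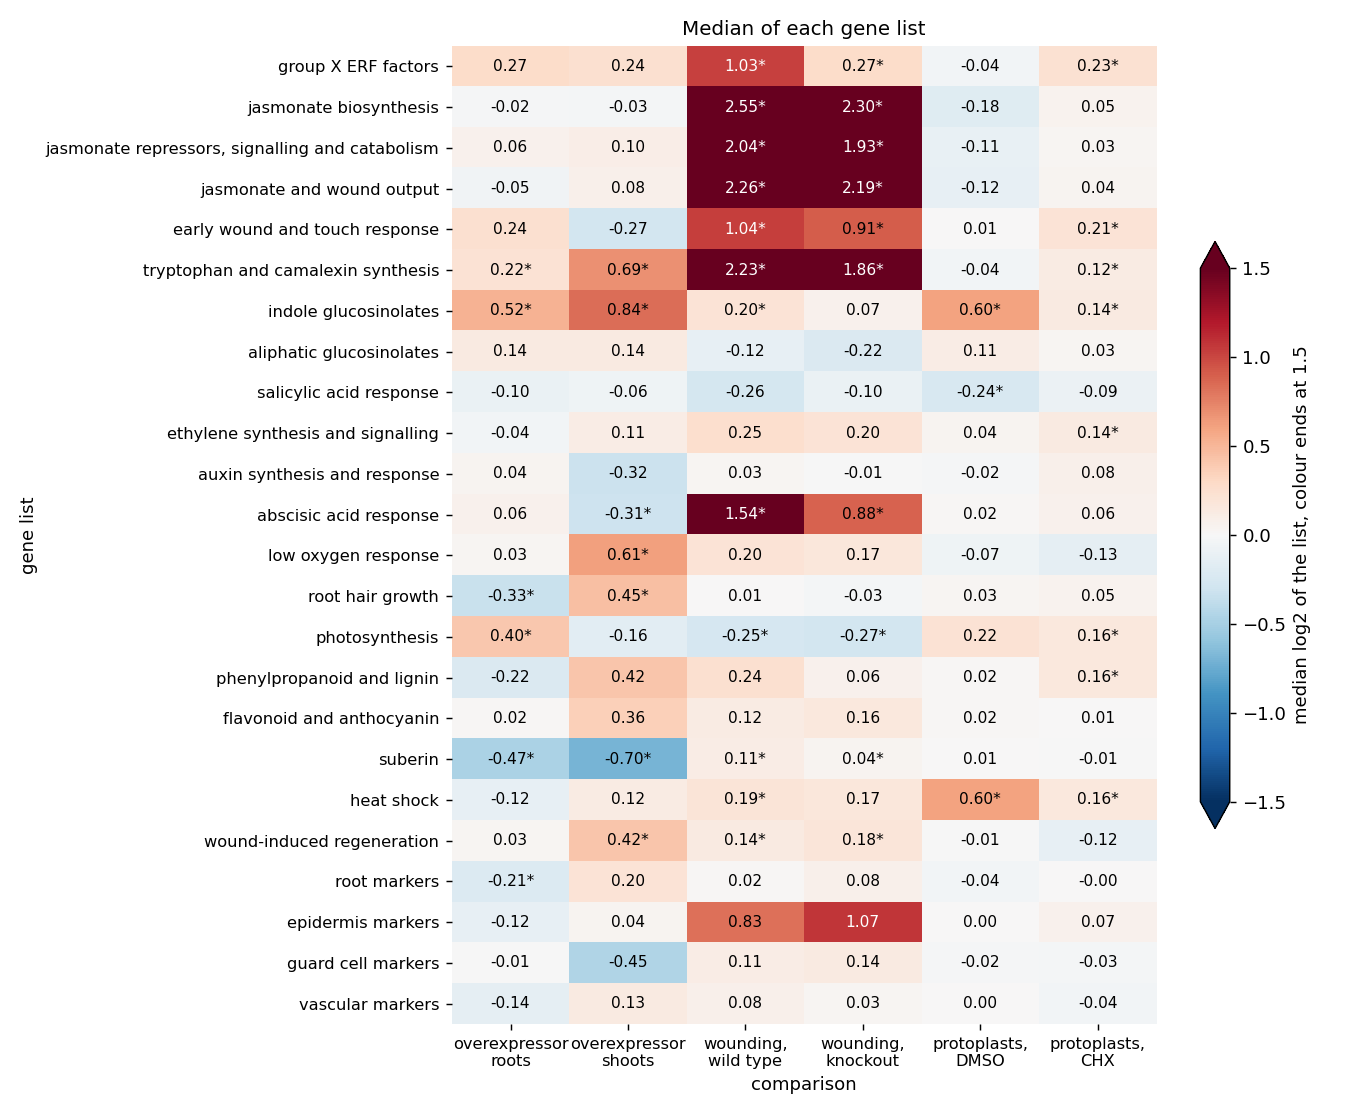
Median log2 ratio (colour and number) of each of the 24 gene lists in each of the 6 direct comparisons, with asterisks where camera gave an adjusted p under 0.05. The jasmonate lists stand between 1.93 and 2.55 in both wounding comparisons and between -0.18 and 0.10 in the others.

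Across experiments the called genes overlapped. Overexpressor roots and shoots shared 196 higher genes where 28.9 were expected by chance, and 81 lower genes where 31.2 were. DMSO protoplasts shared 77 higher genes with roots (15.2 expected) and 180 with shoots (39.2 expected). The genes called with CHX shared 18 with roots (0.775 expected), 20 with shoots (2.02 expected) and 11 with wounded wild type (3.54 expected, adjusted p = 0.00086), by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over a family of 60 tests, in which genes are not independent. Genes higher in shoots and in wounded wild type numbered 283 (133 expected) and those lower in both 115 (45.1 expected). Against these stood 55 higher in shoots and lower on wounding (65.1 expected) and 118 lower in shoots and higher on wounding (92.2 expected, adjusted p = 0.0085). For roots genes higher in both exceeded chance, at 115 (50.9 expected), and so did those in opposite directions, with 113 lower in roots and higher on wounding (79 expected) and 48 the other way (25.1 expected), while 28 were lower in both (39 expected, adjusted p = 0.098). The wounded knockout overlapped too, with 258 higher genes for shoots (114 expected), 99 for roots (43.5 expected) and 8 of those called with CHX (3.02 expected, adjusted p = 0.014). DMSO protoplasts shared 100 higher genes with wounded wild type (70.2 expected), but 92 genes higher in protoplasts were lower on wounding (34.4 expected). All comparisons share each gene's estimate of spread, which by itself makes calls coincide in either direction. Genes higher in all 6 comparisons were AT5G44575 (mean log2 3.71), SS3 (3.46), AT5G44570 (2.51), AT5G44574 (2.30), GPAT7 (1.38) and the glucosinolate transporter gene GTR1 (1.32), and another 9 genes were higher in 5, such as AT5G44572 and ST2A. Genes lower in 4 comparisons numbered 8, led by CYP71B7 (mean -1.25), AT1G18020 (-1.05) and EXPB3 (-0.95), all in both tissues of the overexpressors and both wounded genotypes.

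Lists without a call by camera in any direct comparison were aliphatic glucosinolates, auxin, flavonoids, epidermis, guard cells and vasculature. In wounded wild type their medians were -0.12, 0.03, 0.12, 0.83, 0.11 and 0.08, with SOT17 (1.18 ± 0.12), IAA2 (1.53 ± 0.15), PAP1, CER3, KAT1 (0.83 ± 0.27) and XCP1 (0.40 ± 0.41) as examples, the last pair not called. In overexpressor shoots they were 0.14, -0.32, 0.36, 0.04, -0.45 and 0.13, with SOT17 (0.81 ± 0.12), TT8 (-1.11 ± 0.34, not called) and HT1 (-0.62 ± 0.16) as examples. Over all genes 1 aliphatic glucosinolate gene rose and 1 fell on wounding in wild type, 2 auxin genes rose and 3 fell, 2 flavonoid genes and 2 epidermis genes rose, and 0 guard cell and 0 vascular genes were called by limma. Adjusted over the list alone the epidermis list had 3 higher and 1 lower, and the other counts were the same.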

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

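All tests of explanations in this part were chosen after the results were seen, while the tests of differences had been planned. Values stand out here where a test found the effect of a comparison to differ between its groups. In the shared model roots and shoots differed in their response to overexpression in 863 genes. The 4 arrays of the seedling slide alone gave 0 by limma, with 3677 at an unadjusted p under 0.05, against 3751 in the shared model. Array weights gave 8 and the slide block 2480, so whether these genes pass depends on how the spread is estimated. The ratio of overexpressor to wild type was higher in roots by log2 3.89 for RAB18 (AT5G66400), 3.58 for EXP3 (AT2G37640), 3.41 for CYP706A1 (AT4G22690), 3.01 for CYP706A2 (AT4G22710) and 3.01 for LEA18 (AT2G35300). The difference was -6.64 for PDF1.2c (AT5G44430), -6.21 for PDF1.3 (AT2G26010), -5.95 for PDF1.2b (AT2G26020), -4.48 for PDF1.2 (AT5G44420) and -3.76 for AT2G14247. The sizes for PDF1.2c, PDF1.2b and PDF1.2 are not exact, since at least 1 root sample was not well above background. List medians differed by 0.39 for abscisic acid response, 0.60 for photosynthesis, -0.50 for low oxygen response, -1.07 for root hair growth, -0.42 for phenylpropanoids and lignin and -0.96 for root markers. None of these 6 lists passed with an estimated correlation (adjusted p = 0.24 to 0.30), and photosynthesis and phenylpropanoids did not pass fry.

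Protoplasts with CHX and with DMSO differed in their response to ERF#111 in 40 genes. The differences were log2 3.04 for PRR1 (AT1G32100), 2.02 for AT3G13650, 1.68 for CYP71B21 (AT3G26190), 1.43 for AT4G23030, -5.47 for AT4G36850, -3.56 for AT5G44572, -3.43 for AT2G34350, -3.36 for ST2A (AT5G07010) and -3.34 for AT5G21280. All these sizes are not exact, since the GFP control was not well above background on at least 1 array of a treatment. List medians differed by 0.23 for jasmonate biosynthesis, 0.20 for jasmonate repressors, signalling and catabolism, 0.19 for jasmonate and wound output, 0.22 for tryptophan and camalexin synthesis, 0.28 for salicylic acid, 0.21 for ethylene, -0.30 for indole glucosinolates and -0.47 for heat shock. None of these 8 lists passed with an estimated correlation (adjusted p = 0.34 to 0.59) or by fry (0.44 to 0.94). Between the wounding responses of both genotypes the median of abscisic acid response differed by -0.40 by camera, with adjusted p = 0.078 with an estimated correlation and 0.40 by fry.

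The first pattern weighed was that both seedling replicates correlated weakly across genes, with r = 0.27 in roots and 0.106 in shoots (Spearman's rho 0.008 and -0.05). A dye bias of each gene shared by all 3 slides was argued against, since the highest r was 0.31 after the dye effect of the other slides was taken off. Noise of probes not well above background was argued against as well, with a highest r of 0.24 without them. That set still held 18585 genes in roots and 15966 in shoots, so noise of probes just above background stays open. The deviations between same-numbered replicates correlated between roots and shoots with r = 0.668, and with r = 0.34 after the dye term common to all arrays was taken off. Differences between both overexpressor lines, other differences between the replicates and a dye bias of the seedling slide alone cannot be told apart here. Line, replicate number and dye changed together.

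The second pattern was that 0 genes passed limma in the difference between both wounding responses, with 121 at an unadjusted p under 0.05 where 1019 are expected by chance. Whether spread of the seedling arrays in the shared variance kept genes other than AtERF#111 from passing stays open. Without the seedling slide 0 of them passed by limma, while array weights called AT2G05540, AT2G41190 and AT5G50360. Without that slide 884 genes had an unadjusted p under 0.05, more than with it but still fewer than chance gives. From the wounding slide alone 1270 did, so including the seedling arrays lowered this count. For AtERF#111 the spread of the seedling arrays may be why it did not pass, as its adjusted p was 0.038 without the seedling slide (range over 18 alternatives 0.0022 to 1). Differences of about 2-fold stay open, since 5% of simulated ones were recovered in this test. Larger differences stay open too, since AtERF#111 differed by log2 -2.18 and did not pass in the shared model.

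The third pattern was the AtERF#111 probe well above background in knockout protoplasts given GFP. Mixing of the ERF#111 sample into the GFP sample was argued against, since it would cap every ratio near that of AtERF#111, at log2 3.52 ± 0.19, while EXPA1 reached 7.54 ± 0.21 and 12 called genes had a larger ratio. A transcript of the mutant allele stays open, since the probe was well above background in 0 of 4 channels of knockout leaves but protoplasts alone could switch it on. Sequence shared with the GFP-HBD plasmid or its carrier was not tested.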

How the results depend on the processing

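Fits without the seedling slide, and list tests under the slide block, the own slide alone or without the seedling slide, and of group X ERF factors without AtERF#111, were chosen after the data were seen, and the others had been planned. Of 10690 alternative values of named genes other than those leaving out an array, 9922 counted as the same, 530 ended a call and 222 gained one. The same were values that kept direction and side of the threshold, or that changed sign by less than 1 SE without a call. Another 14 changed sign by 1 SE or more without a call, and 2 changed sign with a call. With the mean of all probes ACO1 in overexpressor shoots turned to -0.36 and GSTF12 with CHX in GFP protoplasts to -0.07. Signal over background of 1.22 to 5.47 limits dim genes most. Where leaving out an array left a group with 1, that array was assumed to vary like the others. Fewer arrays enter the fits of a slide alone and of leaving out arrays, and a 2-fold minimum removes small changes by its construction. For the other alternatives the cause was not tested.

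With the scanner's log ratio the count of called genes was 595 in overexpressor roots, 1231 in shoots, 105 with CHX, 493 in the root and shoot difference and 1 in the wounding difference. Without an offset it was 485, 1037, 52 and 210 in the first 4 of these. Median centring gave 682 in roots, 1915 in the wounded knockout, 441 with DMSO, 266 in the root and shoot difference, 15 in the CHX and DMSO difference and 1 between wounded genotypes. Scaled spreads gave 599 in shoots, 2025 with DMSO, 208 with CHX, 460 in the root and shoot difference and 166 in the CHX and DMSO difference. A strict filter gave 417 and 22 in these differences, and the model without a dye term 24 in the latter. Without background correction AtERF#111 in the wounded knockout was 0.08.

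The slide block, which also accounts for the pairing of replicates, gave 2310 in roots, 4851 in shoots, 5105 in wounded wild type, 4656 in the wounded knockout, 2346 with DMSO, 89 with CHX, 2480 in the root and shoot difference and 108 in the CHX and DMSO difference. The 4 arrays of a slide alone gave 534, 915, 7134, 6493, 3909, 334, 0 and 699 in the same order, the 0 by limma with 3677 at an unadjusted p under 0.05, and 1567 for CHX in GFP protoplasts. Array weights gave 599, 65, 7985, 6284, 2716, 345, 8 and 578, and 4 in the wounding difference. Without the seedling slide the counts were 6781 in wounded wild type, 6213 in the knockout, 4260 with DMSO, 286 with CHX, 826 in the CHX and DMSO difference, 1 in the wounding difference and 1 between wounded genotypes. With a 2-fold minimum they were 604 in roots, 811 in shoots, 1666 and 1434 in wounded wild type and knockout, 354 with DMSO and 4300 for CHX in GFP protoplasts. That minimum left 2 lower genes shared by roots and DMSO protoplasts and 0 by shoots and DMSO protoplasts, by overlap of limma calls, where 20 and 14 had been shared.

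Leaving out single arrays gave 261 to 637 in roots, 1901 to 5623 in shoots, 864 to 1218 in wounded wild type, 835 to 1057 in the wounded knockout, 67 to 163 with DMSO and 7 to 12 with CHX. It gave 277 to 4419 in the root and shoot difference, 0 in the wounding difference by limma, 0 to 16 in the CHX and DMSO difference, 0 to 5 between unwounded and 0 to 19 between wounded genotypes and 5757 to 6567 for CHX in GFP protoplasts. With an estimated correlation 0 lists passed camera in roots, shoots, DMSO, CHX and each of the 3 differences, 6 in wounded wild type and 5 in the wounded knockout. By fry 11 passed in shoots, 1 with CHX, 0 in the wounding difference and 0 in the CHX and DMSO difference.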

Other observations

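The tests of the iron list and of the genes called with CHX were chosen after the data were seen, and the genes in this part were chosen after their values were seen. In overexpressor roots 12 of 25 measured iron uptake genes fell and 0 rose by limma, among them BHLH101 (log2 -2.39 ± 0.39, n = 2 arrays), NAS2 (-2.37 ± 0.40), NAS1 (-2.32 ± 0.34), MTPA2 (-1.90 ± 0.34) and F6'H1 (-1.08 ± 0.14), besides IRT1 and FRO2. In shoots 9 of the 25 rose and 0 fell by limma, such as BHLH100 (1.95 ± 0.47), BHLH39 (1.75 ± 0.33), BHLH38 (1.54 ± 0.31), ABCG37 (1.34 ± 0.14) and IRT2 (1.15 ± 0.25). BHLH38, BHLH39, BHLH100 and BHLH101 encode transcription factors of the iron deficiency response, and NAS1 and NAS2 nicotianamine synthases.

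A run of neighbouring gene numbers stood out. AT5G44570, AT5G44574 and AT5G44575 were higher in all 6 direct comparisons, with mean log2 of 2.51, 2.30 and 3.71, and AT5G44572 in 5 (mean 2.49). AT5G44575 rose alike on wounding in wild type (4.96) and in the knockout (4.96). AT5G44540 was higher in overexpressor roots (4.17), shoots (4.23) and DMSO protoplasts (2.36) but stood at -0.01 and 0.08 on wounding.

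Iron uptake genes as a group may be lower in overexpressor roots. Without IRT1 and FRO2 21 of the other 23 genes were below 0 there, with p = 0.02 with an estimated correlation and 0.002 by fry. In shoots their median was 0.64 (p = 0.12 with an estimated correlation and 0.016 by fry), so a rise of the group there stays open, and in the root and shoot difference -1.56 (0.012). Of all 25 genes 7 were below 0 in shoots, 10 on the array of line ERF#111-OE2 and 4 on that of line ERF#111-OE1. With all 25 genes the median in roots was -1.02, and it was -1.51 on the array of line ERF#111-OE2 and -0.55 on that of line ERF#111-OE1. Other root genes moved alike, with medians of -0.21 in roots and 0.20 in shoots for root markers, among them IRT1, and of -0.33 and 0.45 for root hair growth, so whether this is particular to iron uptake stays open.

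Genes raised by ERF#111 with CHX may respond less to wounding in the knockout. The 32 genes other than AtERF#111 had a median of -0.04 in the wounding difference, 21 of them below 0, with p = 0.15 with an estimated correlation and 0.19 by fry, so this stays open.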
